A study of Escherichia coli str. K-12 substr. MG1655 with 12 samples.

How the data were processed

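Gene expression was measured on 12 two-colour microarrays of Escherichia coli K-12 MG1655, the sequenced laboratory strain. Each array carried RNA of cells exposed to volatile organic compounds (VOCs) released by Bacillus in one dye and RNA of control cells of the same time point in the other. There were 4 arrays at each of 6, 12 and 24 h. Per the labels, total RNA was extracted with a column kit and 1.5 µg was labelled directly with Cy3 or Cy5. The labels put VOC RNA in Cy5 on the 4 arrays of 6 h and on replicates 1 and 2 of 12 and 24 h, and in Cy3 on replicates 3 and 4 of 12 and 24 h. The file names show that replicates 1 and 2 of a time were arrays of 1 slide (slide 1 below) and replicates 3 and 4 arrays of another (slide 2), so that the 12 arrays lay on 6 slides. Nothing in the labels says that the 4 arrays of a time came from separate cultures: p-values therefore measure only the spread between these arrays, which may be technical. Each time was scanned on a day of its own, and the 6 h slides on another scanner of the same model, so that time and scan batch cannot be told apart. VOC and control RNA shared each array, so that no ratio within a time compares batches.

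Per the file headers, the authors read the spots with GenePix Pro 6.0.1.25 and applied no normalization. The deposited scanner values are the foreground and local background intensity of each spot in red (635 nm, Cy5) and green (532 nm, Cy3). Each array held 5776 spots in 16 printing blocks. Of these, 1000 were control, blank, empty or non-coding spots and were left out of the tests, after background correction and at weight 0 in the loess fit. The other 4776 were probes, of which 4299 carried a b number (the locus tag of the strain) and 477 did not. The b numbers of 4213 probes were found in a gene table of assembly ASM584v2, which gave the symbols used here, and 86 probes with a b number kept the name in the files. No genome build was given in the sources used here, so no coordinates are printed. For 30 loci with 2 or more probes, the probe with the highest mean intensity stood for the gene in gene lists.

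The authors' value table of the series holds log2 ratios per array whose method is not stated. Set against the scanner log2 ratios, its columns correlated at 0.969 to 0.991 in size with slopes of 1.03 to 1.18 in size, so its scale is log2. Its medians were -0.0725, -0.0695, -0.175 and -0.173 for replicates 1 to 4 at 6 h, 0.0144, 0.0101, -0.0233 and -0.0291 at 12 h, and 0.0398, 0.0426, 0.0208 and 0.0398 at 24 h. How it was centred stays unknown. Its direction stays unknown too, because its sign runs against the labelled dyes on slide 1 of 6 h and on slide 2 of 12 h and with them elsewhere. It was used only as an alternative.

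Signal differed between arrays. Between 71.9% and 99.2% of probes lay above local background plus 2 SD in at least 1 channel (71.9 to 93.4% at 6 h, 91.0 to 96.3% at 12 h, 97.3 to 99.2% at 24 h). Median foreground was 327.5 to 756 in red and 360.5 to 1063 in green, over local background of 31 to 64 and 64 to 126. At most 2 probes of an array were saturated. Spots with a negative quality flag in the files had weight 0. They made up 0.0838 to 5.21% of probes at 6 h, 15.3 to 18.2% at 12 h and 0.544 to 15.8% at 24 h.

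Median intensities were corrected with normexp (offset 50) and normalized within each array by loess in limma 3.58.1 (R 4.3.3, statmod 1.5.0). The log2 ratios of the 12 arrays entered 1 limma fit with a coefficient per time point and a dye term per probe, estimated where both dye orientations were present. The slide was a random block (duplicateCorrelation). Probes with a Benjamini-Hochberg adjusted p under 0.05 over all probes tested were called (two-sided). The differences between times were contrasts of the same fit, and an F test covered the 3 times together. That F test is approximate because spots were missing, and it used probes measured at each time. Means ± SD beside a gene are over the 4 arrays of a time, turned so that a positive value means higher in VOC-exposed cells. SEs are those of the fit.

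On the labelled dyes the slides of 6 h ran in opposite directions (r = -0.767 over 4574 probes), which leaves the direction at 6 h unsettled. Each comparison was therefore fitted with the dyes as labelled, and again with the sign of slide 1 of 6 h turned. With slide 2 turned in its place every 6 h value has the opposite sign. The estimated correlation within slides was 0.910 as labelled and 0.715 with slide 1 turned.

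Shifts of 21 lists holding 682 genes (flagella and chemotaxis, RpoS-dependent stress, acid resistance, the SoxRS, MarA and Rob regulon, OxyR and peroxide stress, drug efflux, heat shock, ribosomal proteins, aldehyde detoxification, glyoxylate and glycolate metabolism, anaerobic respiration, the TCA cycle and aerobic respiration, nitrogen limitation, iron uptake, curli and biofilm matrix, colanic acid, sugar transport, amino acid biosynthesis, the SOS response, envelope stress and porins, and transcription regulators) were tested with camera at a preset inter-gene correlation of 0.01, for lists of at least 5 measured genes. The p-values were adjusted over lists and times (or differences) together. The test was repeated with the correlation estimated from the residuals, for the times and for the differences between times. Those residuals were of all 12 arrays, so the opposed slides of 6 h entered each estimate. The estimate was 0.871 as labelled and 0.165 with slide 1 turned for ribosomal proteins, and 0.123 and 0.170 for iron uptake. An estimate under the preset 0.01, as for colanic acid as labelled (0) or amino acid biosynthesis turned (2.97e-04), makes the repeat the laxer test before adjustment. A further test was fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes.

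The groups, the tests, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The exceptions are the turned slides, the directions of the value table, the fit of 12 h and 24 h alone, the foreground mean, the estimated correlation for differences and the replicate block within a time, which were chosen after seeing the data. The rule took, per time, the 10 largest rises and 10 largest falls past the threshold with 1 sign on the 4 arrays. Where fewer than 10 passed, it took those that passed and then up to 5 per direction by moderated t. It also took the 5 largest per direction for each difference between times, the 4 members of each list with the smallest p, and the regulators listed. The genes printed are a subset of these, chosen after their values were seen. Other alternatives covered the dye term, the slide block, slide averages, background correction, normalization, dim probes, quality flags, array weights, the eBayes options, a 2-fold threshold, the replicate number as a block, and leaving out each array or slide.

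The fit was tested on simulated data with the real design and 200 changed probes in each of 5 simulations. The 3 times were given the same spread per probe and the same correlation within slides, as estimated by the fit. In the data the opposed slides of 6 h raise both, and the correlation was 0.210 from the 12 and 24 h arrays alone. The shares below may therefore not hold for 12 and 24 h. As labelled, 62.4% of probes changed by log2 1 at 24 h were recovered (14.8% at 0.5, 94.4% at 2, 98.4% at 3). For 12 h the share at log2 1 was 64.4% and for 6 h 50.8%. With slide 1 turned, 97.6% were recovered at 6 h and 98.4% at both 12 and 24 h, again at log2 1. Of the calls, 9.57% were false at 24 h, 11.1% at 12 h and 10.3% at 6 h as labelled, and 9.17%, 10.1% and 12.0% with slide 1 turned, above the nominal 5%. The correlation within slides was underestimated there (0.874 to 0.878 for a simulated 0.910, and 0.628 to 0.641 for 0.715). A list shifted by 0.5 was called in 5 of 5 simulations and 0 of 100 unshifted lists were called by camera. The simulated genes varied independently of each other, whereas those of real lists vary together (estimated correlation 0.871 for ribosomal proteins as labelled). The simulation therefore cannot show how often camera calls an unshifted list in these data.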

Results

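Expression profiles of E. coli MG1655 were collected at 6, 12 and 24 h of exposure to Bacillus VOCs, each set on the same array against control cells of that time. The design asks which genes differ between exposed and control cells at each time, and whether the response differs between times. The 4 arrays of a time, on 2 slides, measured 4772 probes at 6 h, 4100 at 12 h and 4756 at 24 h. The arrays of a slide correlated over probes at 0.990 and 0.993 at 6 h, 0.875 and 0.869 at 12 h, and 0.929 and 0.950 at 24 h. Probes are not independent replicates. Between the slides of a time, with the dyes as labelled, the correlation was 0.749 at 12 h, 0.824 at 24 h and -0.767 at 6 h. The labelled dyes therefore give the values of 12 and 24 h a direction that both slides share, and those of 6 h none. The opposed slides of 6 h also widen the error estimate that the 3 times share, so that counts are given both as labelled and with slide 1 of 6 h turned.

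At 24 h, VOC-exposed cells had more transcript of 5 curli genes, whose products form the adhesive amyloid fibres of biofilms. csgB (b1041), the nucleator subunit, rose 9.03-fold (log2 3.17 ± 0.13, SD, n = 4 arrays, adjusted p = 5.1e-07), and csgA (b1042), the main subunit, rose 6.9-fold (2.79 ± 0.19, adjusted p = 4.03e-05). The secretion genes csgF and csgE rose by log2 1.58 and 1.29. The largest fall was that of zraP (b4002), a periplasmic zinc-responsive chaperone, which was 72.2-fold lower (-6.17 ± 0.86, SD, n = 4, adjusted p = 9.73e-06). Genes of hydrogenase 1 fell too, such as hyaC (-3.48 ± 0.20, adjusted p = 9.73e-06) and hyaE (-2.71 ± 0.26, adjusted p = 0.00184).

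Iron uptake was raised at 24 h on both slides (list medians 0.47 and 0.75). Of its 34 genes, 13 rose and 0 fell (17 rose when adjusted over the list alone), with a median log2 of 0.55 (camera adjusted p = 5.51e-18, and adjusted p = 1.19e-04 with an estimated correlation). exbB and exbD, which with tonB energise transport across the outer membrane, each rose by 1.50 (SD 0.24 and 0.18, n = 4), tonB by 1.28 and the enterobactin synthesis gene entE by 1.29. The ferric siderophore receptor gene fhuE rose by 1.38. Ribosomal protein genes were positive in 54 of 54 cases, with a median of 0.82 over both slides (0.86 and 0.79 on each). That median was 0.42 with median centring. Over all probes 13 of them rose, and 49 when adjusted over the list alone (camera adjusted p = 3.88e-28, adjusted p = 0.25 with an estimated correlation). rplS rose by 1.13 ± 0.02, rpsP by 1.10 ± 0.05 and rplW by 0.94 ± 0.08. Of the 22 heat shock genes, dnaK, the Hsp70 chaperone, passed over all probes (1.04 ± 0.17) and 4 rose when adjusted over the list alone. The heat shock median was 0.32, and 0.01 with median centring (camera adjusted p = 8.98e-04, and adjusted p = 0.0216 with an estimated correlation).

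Acid resistance at 24 h had 3 of 20 genes raised (4 when adjusted over the list alone): gadE, the activator of the glutamate-dependent system, by 2.09 ± 0.66, yhiD by 1.08 and the efflux gene mdtE by 0.83. Its median was 0.24 (0.14 and 0.59 on the slides), and 0.54 with median centring (camera adjusted p = 0.00124, adjusted p = 0.632 with an estimated correlation). The curli and biofilm list gave a median of -0.08, which turned to 0.15 with median centring, against a mean of 0.32 and an upward camera test. In it 5 of 23 genes rose (6 rose and 2 fell when adjusted over the list alone; adjusted p = 5.86e-04, and adjusted p = 0.613 with an estimated correlation), and the 5 were csg genes. The list's median was -0.12 on slide 1 and 0.11 on slide 2. In flagella and chemotaxis 3 of 54 genes rose, over all probes and when adjusted over the list alone: flhD (1.03) and flhC (0.71), which encode the master regulator, and the rod gene flgC (0.76). The flagellar median was 0.11, and 0.35 with median centring (adjusted p = 0.0105, adjusted p = 0.195 with an estimated correlation). The porin genes ompC and ompF rose by 1.43 and 1.19 and ompW fell by 2.12. The porins and envelope stress list gave no call (adjusted p = 0.747), and its median of 0.05 turned to -0.34 with median centring. mepS, a cell wall endopeptidase gene, rose by 1.52, and yjjZ, of unknown function, by 1.56.

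Anaerobic respiration and fermentation had 4 of 38 genes lowered at 24 h (6 when adjusted over the list alone), with a median of -0.25 (camera adjusted p = 1.34e-06, adjusted p = 0.464 with an estimated correlation). These were hyaA (-3.05) and hyaB (-3.27) of hydrogenase 1, and hybO (-1.80) and hybC (-0.96) of hydrogenase 2. Outside the list, hyaD fell (-3.07), as did nrdD, the anaerobic ribonucleotide reductase gene (-2.68 ± 0.21, n = 4, adjusted p = 1.17e-05). The genes yahF, yahG and yahC, of poorly known function, fell to -3.67, -3.05 and -2.78. In the TCA cycle and aerobic respiration list, 5 of 42 genes fell and 2 rose (13 and 4 when adjusted over the list alone), with a median of -0.58, and -0.99 with median centring (adjusted p = 0.0327, adjusted p = 0.805 with an estimated correlation). The 5 were nuo genes of NADH dehydrogenase I, such as nuoM (-1.11) and nuoI (-0.97), and the 2 were ATP synthase genes, such as atpH (0.74). Peroxide stress had 2 of 18 genes lowered, over all probes and when adjusted over the list alone (median -0.24, and -0.66 with median centring, adjusted p = 0.0437, adjusted p = 0.805 with an estimated correlation). One of them was the manganese transporter gene mntH (-1.28). Amino acid biosynthesis had 6 of 70 genes lowered and 2 raised (8 and 5 when adjusted over the list alone) and no call as a list (adjusted p = 0.461), with a median of 0.01 (-0.01 with the foreground mean) against a mean of -0.04. trpE of tryptophan synthesis (-2.04) and ilvN and ilvB of branched-chain synthesis (-1.75 and -1.72) fell, and asnA, an asparagine synthetase gene, rose by 1.28.

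**Figure D1:**
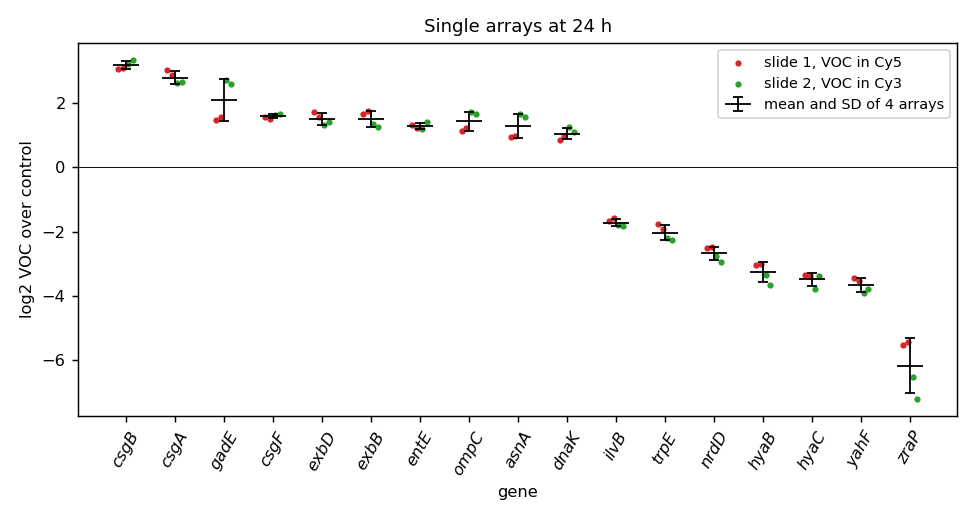
Log2 ratio of VOC-exposed over control cells on single arrays at 24 h for 17 genes, with points for arrays (slide 1 with VOC RNA in Cy5, slide 2 with VOC RNA in Cy3) and the mean and SD of 4 arrays. csgB (3.17) and csgA (2.79) lie highest and zraP (-6.17) lowest, with 1 sign on the 4 arrays of each gene shown.

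As labelled, the remaining lists had no camera call at 24 h. In RpoS-dependent stress (median -0.20, adjusted p = 0.48), nitrogen limitation (-0.42, adjusted p = 0.214), glyoxylate and glycolate metabolism (-0.07, adjusted p = 0.747), sugar transport (-0.11, adjusted p = 0.545), colanic acid (0.06, adjusted p = 0.506) and the SoxRS, MarA and Rob regulon (adjusted p = 0.951), 0 genes passed limma over all probes and 0 when adjusted over the list alone. Aldehyde detoxification had 1 of 19 genes lowered (median -0.37, adjusted p = 0.0606; 1 raised and 1 lowered when adjusted over the list alone). Drug efflux (adjusted p = 0.641), the SOS response (adjusted p = 0.506) and the regulators (adjusted p = 0.951) had 0 genes past the threshold over all probes as labelled, and 0, 1 and 1 when adjusted over the list alone. The SOS median of 0.04, which turned to -0.27 with median centring, stood against a mean of -0.10. The regulator gene fis, a growth-phase nucleoid protein, stood at 1.50 ± 0.23 and missed the threshold as labelled (adjusted p = 0.0518).

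With slide 1 of 6 h turned, nitrogen limitation was called lower at 24 h, with 15 of 29 genes lowered and 1 raised (15 and 2 when adjusted over the list alone; camera adjusted p = 0.0063, adjusted p = 0.155 with an estimated correlation). The others had no call there either (adjusted p from 0.0607 to 0.832), but more of their genes passed. RpoS-dependent stress had 13 genes lowered and 3 raised (14 and 4 when adjusted over the list alone), with a median of -0.60 with median centring. Aldehyde detoxification had 8 lowered and 2 raised (9 and 2 adjusted over the list alone). Sugar transport and the SOS response each had 6 lowered and 2 raised, glyoxylate metabolism 4 and 0, and the SoxRS regulon 2 and 2, with the same counts when adjusted over the list alone. Drug efflux had 4 lowered and 2 raised (2 and 2 adjusted over the list alone), the regulators 4 and 4 (5 and 4), and colanic acid 0 and 1 (0 and 0).

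In total 82 probes rose and 89 fell at 24 h as labelled, of 4756 tested with limma, against 25 and 198 with median centring. With slide 1 of 6 h turned, 552 rose and 677 fell, against 567 and 1025 with median centring, and the 171 calls were among them with the same sign. There 53 of 54 ribosomal protein genes rose (adjusted p = 2.78e-05 with an estimated correlation), as did 20 of 34 iron uptake genes. Heat shock had 10 genes higher and 1 lower there, acid resistance 9 and 2, flagella 11 and 0, and curli and biofilm 6 and 4 (12 and 1, 9 and 2, 7 and 0, and 6 and 4 when adjusted over the list alone). Anaerobic respiration had 15 lower and 2 higher, the TCA cycle list 22 and 10, and peroxide stress 6 and 0 (16 and 2, 23 and 13, and 6 and 0 when adjusted over the list alone). Averaging the arrays of a slide first left 0 probes as labelled (435 at an unadjusted p under 0.05) and 566 with slide 1 turned. As labelled, limma called 2 probes without slide 1 of 24 h and 4 without slide 2. It called 50 and 45 without slide 1 or 2 of 12 h, 2226 and 2189 without slide 1 or 2 of 6 h, and 107, 111 or 2195 without replicate 1 or 2 of 24 h or without the 6 h arrays.

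At 12 h, genes of flagella, motility and chemotaxis were lower in VOC-exposed cells. Each of the 54 measured members had a negative log2 ratio, with a median of -0.96, and the list fell on both slides (-1.01 and -0.92; camera adjusted p = 1.72e-89, and adjusted p = 6.88e-53 with an estimated correlation). As labelled 0 members passed over all probes and 49 fell when adjusted over the list alone, and with slide 1 of 6 h turned 52 fell over all probes. Examples with slide 1 turned are the motor switch gene fliG, which fell by 1.57 (SD 0.08, n = 4 arrays, adjusted p = 1.61e-05), and the export gene fliH, which fell by 1.48 (SD 0.09, adjusted p = 2.22e-05). As labelled the chemotaxis coupling gene cheW stood at -1.07 ± 0.11 and, like flgC and the hook gene flgE, had an adjusted p = 0.0515.

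The TCA cycle and aerobic respiration list was also lower at 12 h, with a median of -0.45 and 39 of 42 members negative (camera adjusted p = 2.09e-12, adjusted p = 0.106 with an estimated correlation). Over all probes 0 of its members passed as labelled, 3 fell when adjusted over the list alone, and 22 fell with slide 1 turned (adjusted p = 0.0200 with an estimated correlation). The ATP synthase gene atpH stood at -0.73 ± 0.16 (adjusted p = 0.0672 as labelled, 1.26e-04 turned). Iron uptake was lower (median -0.26, adjusted p = 2.04e-04, adjusted p = 0.223 with an estimated correlation), with fhuD at -0.66 (adjusted p = 0.486). Sugar transport was lower too (median -0.12, adjusted p = 0.0027, adjusted p = 0.805 with an estimated correlation). Its trehalose genes treB, the importer, and treC, the hydrolase, stood at -1.59 ± 0.18 and -1.07 ± 0.25 (adjusted p = 0.0567) and both fell when adjusted over the list alone. treB fell over all probes with slide 1 turned (adjusted p = 4.25e-05). Amino acid biosynthesis (-0.17, adjusted p = 0.00288, adjusted p = 0.632 with an estimated correlation) and ribosomal proteins (-0.13, adjusted p = 0.0327, adjusted p = 0.883 with an estimated correlation) made up the other two lists lowered. The ribosomal median was -0.25 on slide 1 and -0.01 on slide 2, which has the opposite dye orientation. Over all probes 7 of 34 iron uptake genes, 10 of 53 sugar transport genes, 12 of 69 amino acid genes and 3 of 54 ribosomal protein genes fell with slide 1 turned (13, 11, 14 and 1 when adjusted over the list alone, with 1 iron uptake gene higher). Of these 4 lists only amino acid biosynthesis kept its call there with an estimated correlation (adjusted p = 1.95e-04). Its estimate of 2.97e-04 lay under the preset 0.01, so the repeat was the laxer test before adjustment.

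The lists raised at 12 h were curli and biofilm (median 0.47, adjusted p = 2.99e-05, adjusted p = 0.366 with an estimated correlation), anaerobic respiration (0.23, adjusted p = 1.69e-04, adjusted p = 0.632 with an estimated correlation), the SoxRS, MarA and Rob regulon (0.08, adjusted p = 0.0327, adjusted p = 0.0612 with an estimated correlation) and RpoS-dependent stress (0.38, adjusted p = 0.0490, adjusted p = 0.883 with an estimated correlation). The SoxRS median was 0.10 on slide 1 and 0.03 on slide 2. soxS, the superoxide response regulator, stood at 0.76 ± 0.07 and rose when adjusted over the list alone (adjusted p = 0.104 over all probes, 6.98e-04 with slide 1 turned). Over all probes 9 of 22 curli and biofilm genes, 6 of 34 anaerobic respiration genes, 2 of 23 SoxRS regulon genes and 3 of 36 RpoS genes rose with slide 1 turned (14, 9, 1 and 3 when adjusted over the list alone). The outer membrane stress gene bhsA stood at 0.83 ± 0.24 (adjusted p = 0.122). Single genes that rose with slide 1 turned include ygeY by 1.72 ± 0.22 (adjusted p = 0.0191), ygfM by 1.34, ygfK by 1.13, the xanthine transporter gene xanQ by 1.10 and hyuA by 0.91, and ssnA passed as well (adjusted p = 0.00558). The transporter gene ynfM and the small protein gene ydfZ rose by 1.10 and 1.15, and the nitrate reductase gene napH and the arsenic repressor gene arsR fell (-1.21 and -1.28). Lists without a camera call as labelled were acid resistance (median 0.23, adjusted p = 0.0605), the SOS response (0.17, adjusted p = 0.0605), aldehyde detoxification (0.14, adjusted p = 0.0957), nitrogen limitation (-0.29, adjusted p = 0.192), peroxide stress (0.21, adjusted p = 0.294), regulators (0.03, adjusted p = 0.356), heat shock (0.06, adjusted p = 0.467), glyoxylate (-0.23, adjusted p = 0.506), colanic acid (-0.07, adjusted p = 0.641), envelope stress (0.06 against a mean of -0.01, adjusted p = 0.803) and drug efflux (-0.07, adjusted p = 0.996). Nitrogen limitation was called lower with slide 1 turned (adjusted p = 0.00125, adjusted p = 0.0844 with an estimated correlation), with 8 of 27 genes lower and 1 higher (12 and 1 when adjusted over the list alone). Acid resistance (adjusted p = 0.0145, adjusted p = 0.36 with an estimated correlation) and the SOS response (adjusted p = 0.0461, adjusted p = 0.0721 with an estimated correlation) were called higher there, with 1 of 19 and 2 of 19 genes higher (1 higher, and 8 higher and 1 lower, when adjusted over the list alone). The other lists of this group had no call, and at most 3 genes in a direction past the threshold over all probes (at most 5, glyoxylate genes lowered, when adjusted over the list alone).

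As labelled, limma called 0 of 4100 probes at 12 h (254 at an unadjusted p under 0.05), and with slide 1 of 6 h turned it called 171 higher and 301 lower. The count was 1702 from the 12 and 24 h arrays alone, 1760 and 1732 without slide 1 or 2 of 6 h, and, with slide 1 turned, 107 and 68 without slide 1 or 2 of 12 h and 0 from slide averages (735 at an unadjusted p under 0.05). With the directions of the authors' value table, which turn slide 2 of 12 h against its labels, limma called 0 (55 at an unadjusted p under 0.05).

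**Figure D2:**
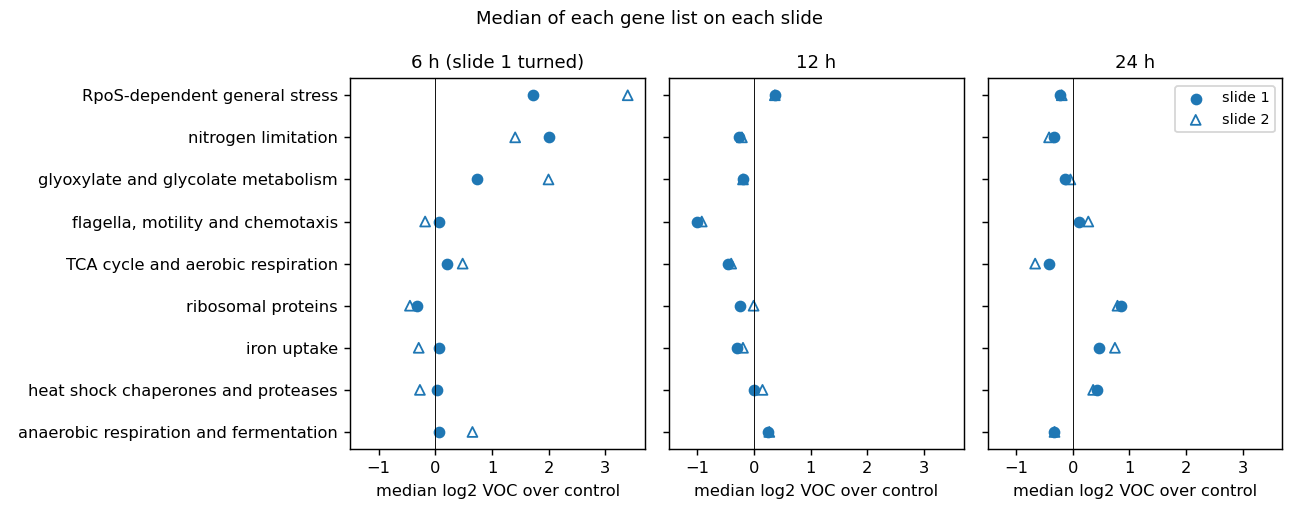
Median log2 ratio of VOC-exposed over control cells of 9 gene lists on each slide at 6 h (slide 1 turned, a direction that is not settled), 12 h and 24 h, with one marker per slide. Flagella lie at -1.01 and -0.92 at 12 h and ribosomal proteins at 0.86 and 0.79 at 24 h, while with median centring the TCA cycle median at 6 h turns to -0.11.

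At 6 h, single genes had large ratios on each slide, but in opposite directions as labelled, where limma called 0 of 4772 probes (54 at an unadjusted p under 0.05). On slide 2, where the labels put VOC RNA in Cy5, astC (b1748) of arginine catabolism had a mean log2 of 5.40, and on slide 1, with the same labelled orientation, of -4.49. The direction at 6 h is therefore not settled. If the cultures responded in opposite directions, the slides share no common effect at all. A turn of 1 slide was chosen because the slides oppose each other. Their agreement after the turn, and the SDs and p-values that rest on it, are therefore in part built in. The values below have slide 1 turned, and with slide 2 turned every one takes the opposite sign. So read, astC stood at 4.94 ± 0.53 (SD, n = 4 arrays, adjusted p = 1.91e-12), astA of the same pathway at 4.63 ± 0.48, and glnK (b0450) and amtB (b0451), of ammonium sensing and uptake, at 4.29 ± 0.24 and 3.97 ± 0.50. On the other side lay btsT (b4354), a pyruvate importer gene, at -2.75 ± 0.59 (adjusted p = 1.5e-08).

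With slide 1 turned, 28 of 29 nitrogen limitation genes were higher (29 when adjusted over the list alone), with a median of 1.54 (2.01 and 1.41 on the slides; camera adjusted p = 7.16e-61, and adjusted p = 1.73e-25 with an estimated correlation). They include the regulator gene nac (3.53) and astE (3.28). RpoS-dependent stress was higher in 36 of 36 genes, also when adjusted over the list alone, with a median of 2.60 (1.73 and 3.39 on the slides; adjusted p = 6.19e-40, and adjusted p = 0.0289 with an estimated correlation). In it the kinase gene yeaG stood at 4.19 ± 0.77, yeaH at 3.83, the pyruvate oxidase gene poxB at 3.14 and rpoS itself, the stationary-phase sigma factor gene, at 1.46 ± 0.42. Glyoxylate and glycolate metabolism was higher in 13 of 19 genes, also when adjusted over the list alone (median 1.37, adjusted p = 1.11e-19, and adjusted p = 3.02e-06 with an estimated correlation), with glcB, glcD and glcA at 3.14, 3.11 and 3.03. Its medians were 0.73 on slide 1 turned and 2.00 on slide 2. Amino acid biosynthesis had 33 of 71 genes higher and 3 lower (35 and 6 when adjusted over the list alone; median 0.42, and 0.26 with the authors' value table, adjusted p = 0.0461, and adjusted p = 0.0263 with an estimated correlation), among them gltD (1.61), gltB (1.59) and serA (1.57). The tryptophanase gene tnaA and its leader tnaC stood at 4.28 ± 2.18 and 4.57 ± 3.07, with an SD set by the slides (tnaA 2.37 and 2.42 on slide 1 against 6.07 and 6.26 on slide 2). yahO, of unknown function, stood at 4.05 ± 2.23, and glaH and lhgD, of glutarate degradation, at 3.97 and 3.97.

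Other lists higher at 6 h with slide 1 turned lost their call with an estimated correlation. Acid resistance had 11 of 19 genes higher and 1 lower (median 0.77, and 1.24 with normexp offset 0, adjusted p = 3.01e-04, adjusted p = 0.155 with an estimated correlation), hdeA at 1.68 among them. Its medians were 0.33 on slide 1 turned and 1.22 on slide 2. Peroxide stress had 9 of 18 higher (0.34, and 0.12 with median centring, adjusted p = 0.0197, adjusted p = 0.155 with an estimated correlation), such as the iron-sulfur assembly gene sufA (0.99). Aldehyde detoxification had 10 of 19 higher and 1 lower (0.32, and 0.16 with the authors' value table, adjusted p = 0.00646, adjusted p = 0.103 with an estimated correlation), such as aldA (2.02). Sugar transport had 28 of 53 higher and 6 lower (0.38, and 0.15 with median centring, adjusted p = 0.0114, adjusted p = 0.483 with an estimated correlation). The TCA cycle list had 21 of 42 higher and 1 lower, such as gltA (1.79), with a median of 0.33 that turned to -0.11 with median centring (adjusted p = 0.0067, adjusted p = 0.418 with an estimated correlation).

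Ribosomal protein genes were lower in 34 of 54 cases with slide 1 turned (38 when adjusted over the list alone; median -0.41, and -0.99 with median centring, adjusted p = 2.0e-09, adjusted p = 0.0672 with an estimated correlation), such as rpsR (-0.82) and rplS (-0.62). Flagella had 16 of 54 genes lower and 6 higher (median -0.04, and -0.42 with median centring, adjusted p = 0.0461, adjusted p = 0.36 with an estimated correlation), with fliR at -0.85 and the flagellin gene fliC at 0.76. The flagellar median was 0.06 on slide 1 so turned and -0.18 on slide 2, of opposite sign. Iron uptake had 9 of 34 lower and 2 higher (-0.17, and -0.37 with the authors' value table, adjusted p = 0.0498, adjusted p = 0.483 with an estimated correlation). Its slides too had opposite signs, with medians of 0.06 on slide 1 turned and -0.29 on slide 2. Of the sialic acid genes, nanC, nanA, nanK, nanT, nanQ and nanE stood at -2.06, -1.91, -1.56, -1.54, -1.47 and -1.46. The glycerate kinase gene garK, the putrescine importer gene plaP and yjaA stood at -1.54, -1.48 and -1.43. Of the regulators, 8 of 22 were higher and 3 lower with no list call (adjusted p = 0.375), arcA at 1.04 and fis at -1.17 among them. No call was made either for anaerobic respiration (16 of 38 higher, adjusted p = 0.0851), curli (9 of 23 higher, adjusted p = 0.0885), the SOS response (9 of 19 lower and 2 higher, adjusted p = 0.0553), heat shock (adjusted p = 0.313), drug efflux (adjusted p = 0.27), the SoxRS regulon (adjusted p = 0.732), colanic acid (median 0.05 against a downward test, adjusted p = 0.708) and envelope stress (adjusted p = 0.983).

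**Figure D3:**
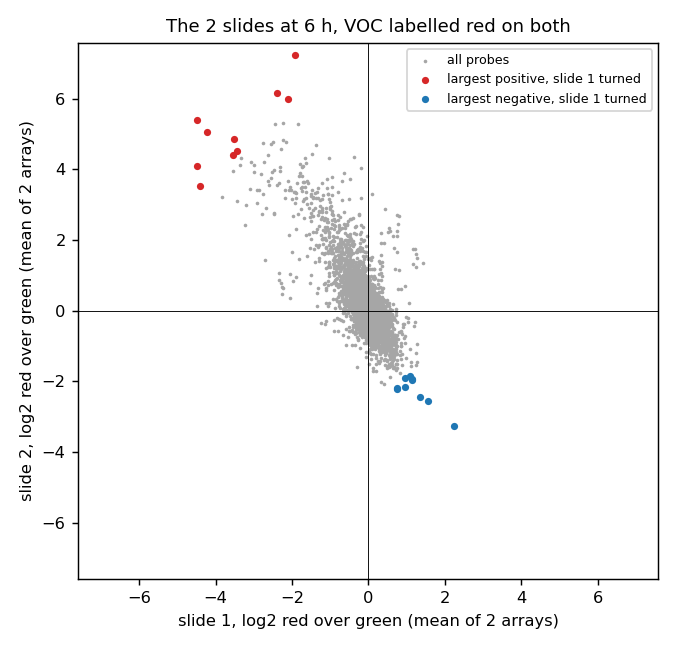
Mean log2 red over green of slide 1 (horizontal) against slide 2 (vertical) at 6 h, one point per probe, with the genes of largest values with slide 1 turned in colour. The slides correlate at -0.767 over 4574 probes although the labels give both the same dye orientation.

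As labelled, the 5 highest genes at 6 h in units of their SE were cysW (1.44), cysP (1.43), cysA (1.40), tsuB (1.37) and tsuA (1.15), each of sulfate or thiosulfate uptake. They were positive on 4 of 4 arrays, each with adjusted p = 0.101. Of the lists as labelled, colanic acid was lower (median -0.12, and -0.20 with the authors' value table, adjusted p = 0.0109, and adjusted p = 0.0197 with an estimated correlation) and envelope stress higher (0.11, which turned to -0.00 with median centring; adjusted p = 6.89e-04, and adjusted p = 0.0177 with an estimated correlation). For colanic acid the estimate was 0, from 5 of 23 genes, so the repeat was laxer than the preset and could not remove its call before adjustment. By fry the adjusted p was 0.766 for colanic acid and 0.0632 for envelope stress. The envelope stress median came from slide 2 (0.23), while that of slide 1 was 0.01 turned, and so of the other sign as labelled. The other 7 calls were lost, with adjusted p = 0.71 (RpoS), 0.632 (acid resistance), 0.632 (anaerobic respiration), 0.883 (sugar transport), 0.254 (flagella), 0.883 (nitrogen) and 0.254 (iron) with an estimated correlation. The split with slide 1 turned was 1113 higher and 739 lower, against 856 and 851 with median centring. It was 826 higher and 1225 lower with the authors' value table, where the median of all probes moved to -0.125. With slide 2 turned, 739 were higher and 1113 lower. Slide 1 and slide 2 alone, without the other, gave 1520 and 2609 calls.

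The response differed between 12 and 24 h in 57 probes that were higher at 24 h and 56 that were lower, of 4096 tested as labelled (26 and 76 with median centring). csgB was 2.56 ± 0.24 (SE) higher, csgA 2.21, ompF 2.21, mepS 2.07 and asnA 2.06, and zraP was -6.01 ± 0.57 (SE) relative to 12 h, ygeY -4.19, hyaB -4.02, hyaC -4.01 and yahF -3.96. The flagellar list moved up from 12 to 24 h by a median of 1.14 (camera adjusted p = 2.26e-28, and adjusted p = 1.43e-16 with an estimated correlation), with 11 of 54 genes past the threshold and 36 when adjusted over the list alone. Iron uptake moved up by 0.96 (adjusted p = 3.32e-17, and adjusted p = 1.16e-04 with an estimated correlation; 8 of 34 genes, 16 adjusted over the list alone). Ribosomal proteins moved up by 0.95, or 0.51 with median centring (adjusted p = 1.36e-20, adjusted p = 0.319 with an estimated correlation; 1 of 54, 37 adjusted over the list alone). Anaerobic respiration moved down by a median of -0.56 (adjusted p = 1.17e-08, adjusted p = 0.239 with an estimated correlation). Aldehyde detoxification moved down by -0.59 (adjusted p = 0.0453, adjusted p = 0.579 with an estimated correlation). With slide 1 of 6 h turned, 609 probes were higher and 639 lower (377 and 824 with median centring), and 112 of the 113 calls were among them. Ribosomal proteins kept their camera call there with an estimated correlation (adjusted p = 3.32e-04), with 53 of 54 genes past the threshold. Aldehyde detoxification and anaerobic respiration did not (camera adjusted p = 0.197 and 0.177). The count as labelled was 0 from slide averages with limma (410 at an unadjusted p under 0.05), 1 without slide 2 of 12 h, 1 without slide 1 of 24 h, 11 without slide 1 of 12 h, 7 without slide 2 of 24 h, and 2256 or 2213 without slide 1 or 2 of 6 h.

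Against 6 h, the direction is again unsettled for the part that 6 h contributes. As labelled, cysA and cysW were lower at 12 h than at 6 h by a log2 of -2.11 and -2.09 (adjusted p = 0.046 for each), and they were the only probes called, 2 of 4758 (128 at an unadjusted p under 0.05). Neither was called with slide 1 turned. Between 6 and 24 h as labelled, 6 probes were higher at 24 h and 29 lower, with csgB at 3.16, csgA at 2.67, entE at 1.71, zraP at -5.61, hyaB at -3.64 and the proline catabolism gene putA at -3.61. With slide 1 turned, 773 were higher at 24 h and 1143 lower (1131 and 864 with the authors' value table), and with slide 2 turned 773 and 445. The glutarate gene lhgD and the transporter gene gabP stood at -6.02 and -5.97, and fis at 2.67, with slide 1 turned. From 6 to 12 h 362 were higher and 837 lower with slide 1 turned (418 and 558 with median centring, 599 and 574 with the authors' value table), against 1016 and 710 with slide 2 turned. In that comparison with slide 1 turned, astC stood at -5.35, tnaC at -5.15, tnaA at -4.91, btsT at 2.82, nanC at 2.04 and nanA at 1.91. Over the 3 times, 92 of 4094 probes changed at any time as labelled and 2399 with slide 1 turned. From slide averages limma called 0 as labelled for 12 against 6 h, 24 against 6 h and any time (81, 193 and 237 at an unadjusted p under 0.05). For 24 against 6 h it called 0 without slide 1 of 24 h, 5 without slide 2, 2 without either slide of 12 h, and 2720 or 1607 without slide 1 or 2 of 6 h. At any time it called 2, 4, 23, 22, 3411 and 3065 without slide 1 or 2 of 24 h, 12 h and 6 h in turn, and 56 to 75 without 1 array.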

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

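The tests of a reversed dye label and of dye bias, and each value with slide 1 of 6 h turned, were chosen only after the result was seen.

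At 6 h the slides, labelled with the same dye orientation, correlated at -0.767 over probes, which argues against dye bias of single probes, since that would move red over green the same way on both slides. A reversed dye label on 1 of the slides may account for it: with 1 slide turned the correlation is 0.767, but that is the same value with its sign changed and cannot be told apart from cultures that responded in opposite directions. Such cultures would have like control channels, yet the green channels, labelled control on both slides, correlated at 0.956, against 0.964 and 0.990 for green with red across slides. The difference to the lower of these was -0.00768 (bootstrap interval over probes -0.013 to -0.0026), which fell short of the bound set beforehand. That interval holds no spread between slides, because only probes were resampled. The red channels correlated at 0.927 between the slides, lower than the other pairs. Both explanations stay open. As to which slide would be turned, the authors' value table runs against the labels on slide 1 of 6 h and with them on slide 2, but it also runs against them on slide 2 of 12 h, where the labelled slides correlate at 0.749, so it does not settle the question.

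Flagellar genes were lower at 12 h. Dye bias would give the list opposite signs on slides of opposite dye orientation, but the slide nearer 0 had a median of -0.92. The loess normalization is argued against by median centring alone, where the median was -0.99. Lower transcription of flhD and flhC, the master regulator genes, may be part of the cause: their mean was -0.42, between the bounds set beforehand, with flhD at -0.12 (adjusted p = 0.998) and flhC at -0.73 (adjusted p = 0.123), so it stays open. The exposure itself, which the design names, stays open as well.

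Ribosomal protein genes were higher at 24 h. A bias of bright spots that remains after loess is argued against by 10000 random lists matched on mean intensity. Among them the list's median of 0.82 lay at percentile 100 (95% of random medians between -0.19 and 0.13, highest 0.45). Members of the random lists were drawn singly, whereas the genes of the list vary together (estimated correlation 0.871 as labelled and 0.165 with slide 1 of 6 h turned). The spread of the random medians may therefore be too narrow. Dye bias is argued against by the slide nearer 0, which had a median of 0.79. The size may in part be set by the normalization, since the median was 0.42 with median centring. No biological explanation was tested.

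The effect of exposure differed between 12 and 24 h as labelled in 113 probes, by the test of the difference itself. The genes past that test were zraP (-6.01), ygeY (-4.19), hyaB (-4.02), hyaC (-4.01), yahF (-3.96), csgB (2.56), csgA (2.21), ompF (2.21), mepS (2.07) and asnA (2.06), among others. The lists were flagella (1.14), iron uptake (0.96), ribosomal proteins (0.95), aldehyde detoxification (-0.59) and anaerobic respiration (-0.56). As labelled, ribosomal proteins, aldehyde detoxification and anaerobic respiration lost their camera call with an estimated correlation (adjusted p = 0.319, 0.579 and 0.239). With slide 1 of 6 h turned, ribosomal proteins kept it (camera adjusted p = 3.32e-04), and aldehyde detoxification and anaerobic respiration did not (0.197 and 0.177). The count of probes was 1248 with slide 1 turned. Between 6 and 12 h 2 probes differed as labelled, cysA (-2.11) and cysW (-2.09), and 1199 with slide 1 turned, such as astC (-5.35), tnaC (-5.15), tnaA (-4.91), btsT (2.82), nanC (2.04) and nanA (1.91). The 2 were not among the 1199. Between 6 and 24 h 35 differed as labelled, with zraP (-5.61), hyaB (-3.64), putA (-3.61), csgB (3.16), csgA (2.67) and entE (1.71), and 1916 with slide 1 turned, with zraP (-6.47), lhgD (-6.02), gabP (-5.97), csgB (3.12), fis (2.67) and csgA (2.56).

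An array stood apart from the others in 2 of 175 groups of 4 values. Chance would give about 1 in 20 for independent values, but arrays of a slide are not independent. The count therefore does not show how alike the arrays were. hyaC at 24 h was -3.79 in replicate 3 against -3.40 to -3.36 in the others, and the anaerobic list at 12 h had a median of 0.22 in replicate 2 against 0.27 to 0.28. Among spots left out of the tests, 97.4% of the readings of the 19 non-coding spots lay above background, against 0.142% for blank spots but 64.5% for negative control spots, so that this share is no measure of specific signal.

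Regroupings of the arrays were counted for each comparison. The 4 arrays of a time have 8 sign patterns, too few for a share under 0.05. There the real count and the highest of the other patterns were 0 and 1852 at 6 h, 0 and 3 at 12 h and 171 and 76 at 24 h as labelled, and 1852 and 0, 472 and 13, and 1229 and 62 with slide 1 turned. The 1852 came with the slides of 6 h opposed, which points to a structure of the samples. For the differences between times single arrays were exchanged, but arrays of a slide are not independent, and whole slides make 3 splits of 2 times, too few for a share under 0.05. As labelled, 3 of 35 splits of arrays gave as many calls for 12 against 6 h (real 2, highest other 519), 2 of 34 for 24 against 12 h (113 and 277) and 3 of 35 for 24 against 6 h (35 and 439). For any time chance cannot be excluded as labelled, where 15 of 100 patterns gave as many (92 and 2399). Most of the other patterns that did so turned 1 whole slide of 6 h against the other. Single arrays of a slide were turned there too, so that share does not measure chance alone. The 519 and 439 came with slide 1 of both times set together, and the 2399 with the slides of 6 h opposed. In the fits with slide 1 turned the counts were 1 of 35 for 12 against 6 h (1199 and 0), 24 against 12 h (1248 and 282) and 24 against 6 h (1916 and 45), and 1 of 100 at any time (2399 and 1460). That slide was turned because of how the 6 h slides correlate, so these counts are no test of chance.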

How the results depend on the processing

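The alternatives with turned slides, the directions of the value table, the foreground mean, the fit of 12 and 24 h alone and the replicate block within a time were chosen only after the data were seen. The counts depend most on the opposed slides of 6 h, which set the correlation within slides at 0.910 as labelled, 0.715 with 1 slide turned and 0.210 from 12 and 24 h alone. Of 147 gene values in the text, 0 changed sign under 16 alternatives, which did not include turned slides or left-out arrays. The fit of 12 and 24 h alone, 1 of the 16, covered 81 of the values. The 2-fold threshold, the eBayes options and quantile normalization between arrays leave each sign as it is by construction. Leaving out dim probes fits the same ratios again. Genes were also named in part for having 1 sign on the arrays of a time. The 0 is therefore in part built in and a weak check. Calls were less stable: 79 of the values lost theirs from slide averages, 18 with median centring and 15 with the 2-fold threshold. The count was 12 with the authors' value table and 10 with normexp offset 0, and up to 17 gained a call (no slide block, array weights). Subtracting no background, eBayes with trend and robust fitting, the foreground mean and leaving out dim probes (4654 were left) moved no count of probes beyond 1.5 times, and quantile normalization of intensities between arrays leaves ratios as they are by construction. Where a cause is not named below, the cause was not tested. The share of probes above background was 71.9% on replicate 3 of 6 h and at least 91.0% on the other arrays, and quality flags left the fewest probes at 12 h (4100 tested).

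Counts as labelled are given for 6 h, 12 h, 24 h, 12 against 6 h, 24 against 12 h, 24 against 6 h and any time, where the reported values were 0, 0, 171, 2, 113, 35 and 92. With slide 1 of 6 h turned they were 1852, 472, 1229, 1199, 1248, 1916 and 2399, and with slide 2 turned the same but for 1726 (12 against 6 h) and 1218 (24 against 6 h). With the directions of the authors' value table they were 1106, 0 (55 at an unadjusted p under 0.05 with limma), 690, 692, 131, 1277 and 1256. Without the slide block, which takes the arrays of a slide as independent, they were 22, 548, 1129, 174, 1082, 584 and 1259. With array weights they were 992, 1376, 1563, 1450, 1781, 805 and 2593. From slide averages, with fewer samples, limma called 0 at each (29, 182, 435, 81, 410, 193 and 237 at an unadjusted p under 0.05). Without the dye term they were 9 (6 h), 41 (12 h), 9 (12 against 6 h), 214 (24 against 12 h), 118 (24 against 6 h) and 191 (any time). With spots of negative quality flag kept they were 5, 32, 5, 185, 55 and 147 in the same order. Print-tip loess gave 4 at 6 h, 6 at 12 h and 5 for 12 against 6 h, normexp with offset 0 gave 2 at 12 h, and it, median centring and the value table gave 0 for 12 against 6 h (limma). The value table also gave 60 for 24 against 12 h and 59 at any time. The fit of the 12 and 24 h arrays alone gave 1702, 2195 and 2216 for 12 h, 24 h and their difference.

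Turning slide 1 and leaving out the slide block gave 2793 (6 h), 1489 (12 h), 2096 (24 h), 2186 (12 against 6 h) and 2121 (24 against 12 h). Slide averages, turned likewise, gave 1122 (6 h), 0 (12 h, 735 at an unadjusted p under 0.05 with limma), 566 (24 h), 262 (12 against 6 h), 521 (24 against 12 h) and 1323 (any time). At 12 h, turned likewise, no dye term gave 244, median centring 255, array weights 980 and the authors' values 289. A 2-fold threshold in addition gave, in the order above, 451, 44, 226, 452, 426, 885 and 611.

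The replicate number as a block gave, in the order above, 5, 0 (284 at an unadjusted p under 0.05 with limma), 179 (159 shared with the 171), 5, 128, 60 and 111 as labelled, and 1391, 212, 856, 772, 851, 1502 and 1819 with slide 1 turned. Between 12 and 24 h same-numbered arrays deviated together in part: the correlation of deviations was 0.382, 0.285, 0.239 and 0.0875 for replicates 1 to 4, and 3 of 4 correlated best with their own number. One pair lay under 0.1, so the numbers were not taken to pair the samples. Replicate number and dye orientation went together at both times, and these deviations were taken without a dye term. A dye effect shared by the times would also make same-numbered arrays deviate together, so the values cannot show paired samples. Pairs with 6 h ran from -0.114 to -0.00607 as labelled and -0.218 to -0.162 turned, and 0 correlated best with their own number.

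List calls as labelled numbered 28. They numbered 5 with the inter-gene correlation estimated, 6 by fry, 26 without the dye term, 20 from slide averages and 27 without dim probes. With slide 1 turned they numbered 35, against 10 with the correlation estimated, 43 by fry, 31 without the dye term, 34 from slide averages and 34 without dim probes.

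Leaving out 1 array or slide gave as labelled 0 to 2609 at 6 h, 0 to 1760 at 12 h, 2 to 2226 at 24 h, 0 to 2227 for 12 against 6 h, 1 to 2256 for 24 against 12 h, 0 to 2720 for 24 against 6 h and 2 to 3411 at any time. The ranges with slide 1 turned were 1520 to 2609, 68 to 1760, 616 to 2226, 454 to 2227, 585 to 2256, 1409 to 2720 and 2087 to 3411. The highest counts came without slide 1 of 6 h. The lowest came without slide 1 of 24 h for 24 h, 24 against 6 h and any time as labelled, without slide 2 of 12 h for 12 h turned, and without slide 1 of 12 h for 12 against 6 h turned. A time left with 1 slide is assumed to vary like the others.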

Other observations

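The values of single genes and the overlaps of times were tested only after the results were seen. At 24 h some genes of sulfate and thiosulfate uptake, chosen after their values were seen, were higher in exposed cells; the pathway was not a fixed list and was not tested as a group. cysW rose by 1.11 ± 0.02 (SD, n = 4 arrays, adjusted p = 0.00868), cysA by 1.10 ± 0.19, cysP by 1.04 ± 0.08 (adjusted p = 0.0129) and tsuA by 1.01 ± 0.18 (adjusted p = 0.00453), and tsuB stood at 0.73 ± 0.10 (adjusted p = 0.0703). Other sulfate uptake genes did not pass, with cysU at 1.14 (adjusted p = 0.122), the binding protein gene sbp at 0.20 (adjusted p = 0.998) and cysZ at 0.17 (adjusted p = 0.921). At 12 h the 5 genes named first stood between -0.71 (cysA) and -0.17 (cysP), with no adjusted p under the threshold. At 6 h those 5 were positive in red over green on both slides, which opposed each other over probes. cysW had 1.24 on slide 1 and 1.59 on slide 2, tsuB 1.43 and 1.35, and cysP 1.22 and 1.74.

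Responses at 12 and 24 h were opposed over probes (r = -0.217, across 4094 probes, which are not independent). With slide 1 of 6 h turned, 80 probes were called higher at 12 h and lower at 24 h, where independent lists would share 28.3, and 76 lower at 12 h and higher at 24 h, against 40.3. Called in the same direction at both times were 15 higher, against 22.9, and 35 lower, against 49.8. Between 6 and 24 h the correlation was -0.345 with slide 1 turned and 0.345 with slide 2 turned. With slide 1 turned 384 probes were higher at 6 h and lower at 24 h, against 158 for independent lists, and 200 the other way, against 85.7, while 84 were higher at both times, against 129, and 43 lower, against 105. Between 6 and 12 h the correlation was 0.197 with slide 1 turned and -0.197 with slide 2 turned. Of probes called with slide 1 turned, 87 were higher at both, against 45.9, and 98 lower at both, against 51.8. Opposed there were 62 higher at 6 h and lower at 12 h, against 81.3, and 13 the other way, against 29.2.

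For 11 genes printed a second time as control spots, in 32 copies, control spots and tested probe differed at 24 h by a median of 0.0894 and at most 0.265 (dnaK), and 9 of 11 had the same sign. At 12 h they differed by a median of 0.0877 and at most 0.168 (ftsL), and 7 of 11 had the same sign. At 6 h with slide 1 turned they differed by a median of 0.226 and at most 0.41 (rpoE), and 9 of 11 had the same sign. At 24 h murI (0.06 on control spots, -0.08 on the probe) and nusB (-0.01 and 0.02) had opposite signs. rpsB stood at 0.45 ± 0.12 (SD, n = 4 arrays) on control spots and 0.45 ± 0.04 on the tested probe, groL at 0.55 ± 0.13 and 0.64 ± 0.18, and dnaK at 0.77 ± 0.09 and 1.04 ± 0.17. Of the non-coding spots, named by the design of the array alone, ncRNAK0042 had 1 sign on the 4 arrays at 12 h (0.45 ± 0.18) and at 24 h (0.98 ± 0.65). At 6 h it stood at 1.18 ± 0.90 with slide 1 turned, while as labelled its slides had opposite signs. cnc0011 stood at -0.78 ± 0.25 at 24 h.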
